A study of Mus musculus with 2 samples.

How the data were processed

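The data were 2 single-cell RNA libraries of sorted mouse liver endothelial cells, control and cirrhosis, each from a pool of 3 mice. Per the labels' protocols, livers were perfused with collagenase, hepatocytes were removed by centrifugation, and live GFP-positive cells were sorted after SYTOX Red staining of dead cells and loaded on a droplet system with the Single Cell 3' v3 chemistry. The deposited tables held UMI counts per gene symbol and cell barcode as whole numbers, not normalized. Per the submitters' processing notes, Cell Ranger and the mm10 build were used, and the version, the annotation and any filter are not given in the sources used here. Each table had 31057 rows, which included rows for eGFP and tdTomato of the reporter. The lowest total per barcode was 500 UMIs in both tables, so the deposited barcodes had been selected at that depth or above. No annotation of cells was used, and cell types were named as described here. Positions are from GENCODE M21 on GRCm38, the assembly mm10 is based on, in which 30464 of the 31057 symbols were found.

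Barcodes needed at least 500 UMIs, at least 300 genes and under 20% mitochondrial counts, and those with over 5% of counts from erythroid markers were left out. This removed 475 control and 666 cirrhosis barcodes. Doublets were scored per library against simulated doublets, and the highest-scoring barcodes, 0.8% per 1000 barcodes, were removed, which was 214 control (4.14%) and 470 cirrhosis barcodes (6.14%). The number of doublets was thus set by loading and not by a threshold on the score. In all, 4953 control and 7191 cirrhosis barcodes were retained.

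Clustering had 2 steps. In the first, counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were taken without haemoglobin genes, and 30 principal components, 20 neighbours and Leiden clustering at resolution 0.5 were used over both libraries together. Clusters were named from marker lists fixed before the data were examined, by their 10 leading genes by fold and by the share of markers above the mean of the other clusters. In the second step, all endothelial-like cells were clustered again with each library centred and scaled on its own, after leaving out cells with over 0.5% of counts from the markers of any other cell type. Mitochondrial, ribosomal protein, haemoglobin, immediate-early, heat shock and interferon-stimulated genes and markers of other cell types did not enter the second clustering. Second-step clusters took the zone or vessel class with the highest mean marker fold if it was at least 0.4 on the log2 scale and 66% of markers were above the other clusters, and otherwise the intermediate class if LSEC markers were. Clusters whose median UMIs lay below the median of all endothelial-like cells of each library divided by 3 stayed unnamed. So did those with 2 or more leading genes of another cell type, if these outnumbered their own. The resolution, for which higher values were also tried, the limits for erythroid and other cell types' transcripts, the thresholds for names, the genes left out and the use of all endothelial-like cells in the second step were set after the data had been seen. They kept 21.6% of control and 22.1% of cirrhosis barcodes out of named classes. No cluster of the classes compared had more markers of another class among its 10 leading genes than of its own.

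For each class, UMI counts were summed per library and expressed as CPM of that sum, and the log2 ratio of cirrhosis over control was given with an exact conditional 95% interval. No test was made, since there was 1 library per group. The comparisons, 25 gene lists, cell type markers and the rule for named genes were fixed before the data were examined. List members needed a mean of 20 CPM and counts in both libraries. A list's median was placed among 10000 random lists of equal size matched on mean expression in 20 bins, as a description of these libraries, and its interval came from 1000 Poisson draws of the counts. Named genes were the members with the largest ratios in each list, up to 4 in main lists and 2 in others, with at least 20 CPM in either library. They were also the 10 highest and 10 lowest of all genes at a mean of 50 CPM with 1 sign in every zone, the 5 highest and 5 lowest by the difference between pericentral and periportal ratios, and the 5 highest and 5 lowest in large-vessel cells. One gene that this rule names is not reported here. Other list members in the text were chosen after their values were seen. A class needed 50 cells per library.

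Scaling by the median of ratios moved the median of all genes by 0.11 in the pericentral class, 0.13 in Kupffer cell-like, 0.38 in hepatocyte-like and -0.74 in B cell-like cells, and by less than 0.1 in the other classes. The ratio and its interval were tested on counts simulated from both whole libraries over 3781 genes. The interval held the true ratio for 95.0% of 100 genes changed 2-fold, 91.0% of 100 genes changed 4-fold and 95.3% of unchanged genes, and each changed gene had the true direction. That simulation held Poisson noise only, without variation between animals. Alternatives fixed beforehand were the scaling, the genes of the denominator, equal weight per cell, a stricter filter (1000 UMIs, 500 genes, under 10% mitochondrial counts), no filter on UMIs, genes and mitochondrial counts, doublets kept, resolutions multiplied by 0.5 and 1.5, no centring, and all list members with a count. Alternatives added after the data had been seen were cells with other transcripts kept, mixed and unnamed endothelial clusters summed with the LSEC-like cells, zone classes weighted equally, cells of 6000 to 12000 UMIs, and control cells of either large first-step cluster alone. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9 were used.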

Results

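Single-cell transcriptomes of liver endothelial cells were measured in control mice and in mice with cirrhosis, and the title of the series asks how liver sinusoidal endothelial cells (LSECs), the fenestrated lining of the hepatic capillaries, differ between zones of the liver lobule. The mice were C57BL/6 animals aged 16 weeks that carried Cdh5-Cre, a recombinase driven by an endothelial promoter, and the mTmG reporter, which switches a cell from membrane tdTomato to membrane GFP after recombination. Cirrhosis was induced with inhaled carbon tetrachloride over 12 weeks, a toxin that injures hepatocytes around the central vein. Livers of 3 mice were pooled per group, live GFP-positive non-parenchymal cells were sorted, and 1 library was made per group. The control library held 5642 barcodes and 45767322 UMIs, with a median of 6865 UMIs and 2881 genes per barcode. The cirrhosis library held 8327 barcodes and 77339928 UMIs, with a median of 8537 UMIs and 3248 genes. With 1 library per group there was no replicate check and no test between groups. The intervals given are 95% intervals that cover counting error only, and the differences describe these 2 libraries. They are exact for single genes and shares, and come from Poisson draws for list medians and their differences between zones.

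LSEC-like cells were the most numerous named class in both libraries, and hepatocyte-like barcodes made up a larger share of the cirrhosis library. LSEC-like cells were 59.7% of the control library (2958 of 4953 retained barcodes, Clopper-Pearson interval 58.3% to 61.1%) and 43.2% of the cirrhosis library (3110 of 7191, 42.1% to 44.4%). Hepatocyte-like barcodes were 4.02% and 17.2%, with median depths of only 1141 and 2001 UMIs. Kupffer cell-like barcodes, named for the resident macrophages of the liver, were 2.44% and 4.13%, and T or NK cell-like barcodes were 5.49% and 3.56%. Lymphatic endothelial-like cells numbered 2 in the control and 66 in the cirrhosis library, which is 0.0404% and 0.918%. Clusters that were mixed, led by the transcripts of another cell type, low in UMIs or unnamed held 21.6% of the control and 22.1% of the cirrhosis library. The mixed endothelial and hepatocyte cluster held 8.44% of the control and 0.0278% of the cirrhosis library, and endothelial cells kept out for other cell types' transcripts held 0.505% and 4.70%. The GFP sort, the spin that removed hepatocytes, the minimum of 500 UMIs and the gap in depth between the libraries can each set these shares. At the lower clustering resolution the LSEC-like share of the control library was 22.2%, because a cluster of 2295 control cells was then named a mixture.

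**Figure D1:**
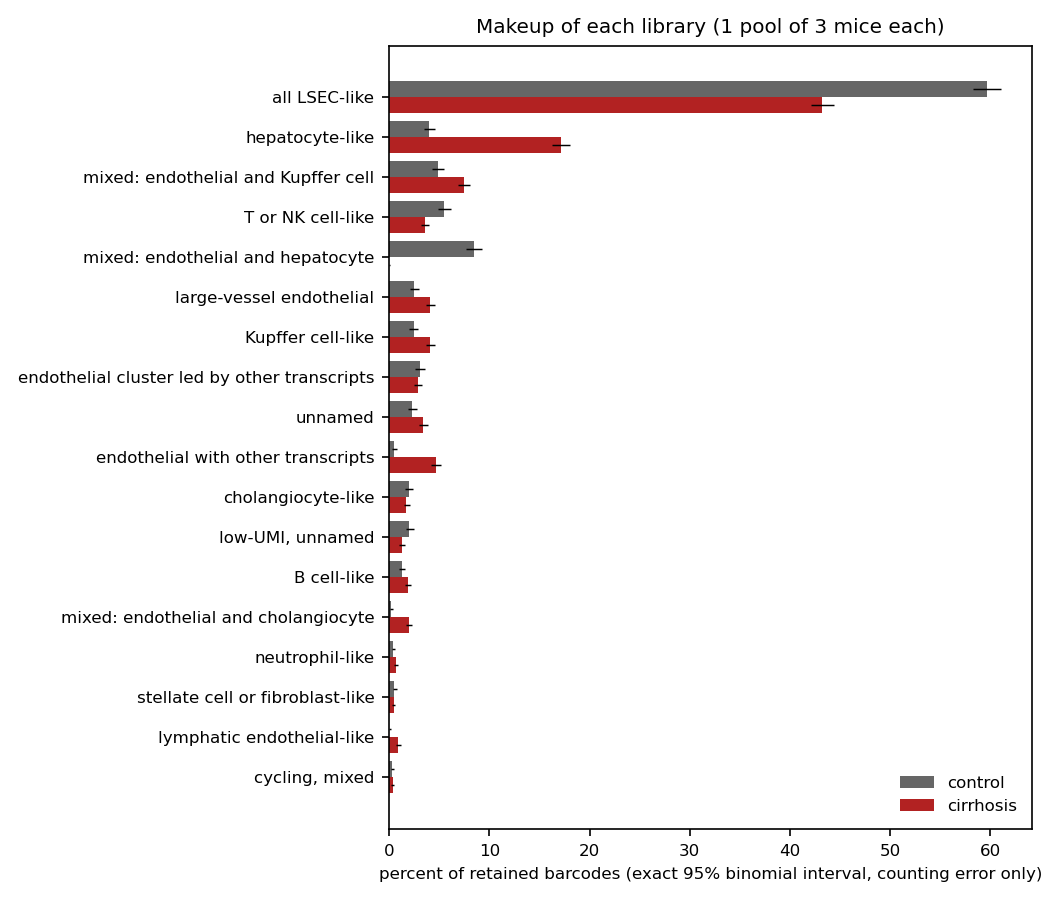
Share of retained barcodes (x axis, percent) in each class (y axis) of the control library (grey, 4953 barcodes) and the cirrhosis library (red, 7191 barcodes), with the 3 LSEC zone classes joined. Bars are single libraries of 3 pooled mice and lines are exact 95% binomial intervals for counting error. LSEC-like cells were 59.7% and 43.2%, and hepatocyte-like barcodes 4.02% and 17.2%.

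The first comparison set all LSEC-like cells of the cirrhosis library against those of the control library. In cirrhosis, genes of continuous capillaries and of basement membrane were higher, while scavenger receptors and LSEC identity genes were lower. The endothelin receptor gene Ednrb stood at 1912 CPM (UMI counts scaled to a common total per class and library) against 73.9 CPM, a 25.9-fold difference (log2 4.69, interval 4.62 to 4.76), and Cd34, a sialomucin of continuous endothelium, stood at 180.3 against 22.6 CPM, 7.97-fold higher (log2 2.99, 2.86 to 3.13). Dnase1l3, a secreted DNase of LSECs, stood at 1916 against 3642 CPM, 1.90-fold lower. The median of all genes with a count in both libraries was -0.08 on the log2 scale. Hepatocyte RNA differed too, with Alb (albumin) at 168 CPM in the cirrhosis and 114.7 CPM in the control LSEC-like cells, and so did depth, with medians of 10034 and 6991 UMIs per cell. The cirrhosis cells came mostly from first-step clusters 0 and 5 and the control cells from first-step clusters 1 and 3, so the libraries separated before zones were assigned.

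Endocytic and scavenger receptors were lower as a group, with 9 of 11 measured members lower, a list median of -0.55 (interval -0.57 to -0.51) and a position at percentile 0.14 of 10000 random lists matched on expression. Stab1, a stabilin that clears modified proteins, stood at 1096 against 1943 CPM (log2 -0.83, -0.85 to -0.81). Mrc1, the mannose receptor, was 1.62-fold lower at 1328 against 2155 CPM, and Lyve1, a hyaluronan receptor, was 1.82-fold lower at 333.7 against 608.2 CPM. The members that went the other way were Cd36, a receptor for fatty acids and thrombospondin, at 1293 against 565.1 CPM (log2 1.19), and Msr1, a macrophage scavenger receptor, at 283.9 against 176.1 CPM. LSEC identity genes were lower in 10 of 10 members, with a median of -0.61 (-0.63 to -0.59, percentile 0.03). Ehd3, an endocytic recycling protein, stood at 2499 against 4575 CPM, Clec1b, a C-type lectin, at 251.5 against 465.9 CPM, and Oit3 at 692 against 1197 CPM. Gata4, a transcription factor that directs LSEC differentiation, differed by -0.03 (-0.08 to 0.02). Markers used to name endothelial classes included 7 of the 13 endocytic genes and 5 of the 10 identity genes.

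Genes of capillarization, the acquisition of continuous-capillary features by LSECs, were higher in 9 of 9 members in the pooled cells, with a median of 0.55 (0.52 to 0.59, percentile 99.9). In the pericentral, intermediate and periportal classes 8 of 9, 5 of 8 and 7 of 9 members were higher, with medians of 0.63, 0.26 and 0.17. Ly6a, the stem cell antigen Sca-1, stood at 1715 against 214.9 CPM (log2 3.00), Vwf, the platelet-binding von Willebrand factor, at 87.9 against 22.6 CPM, and Plvap, the protein of endothelial diaphragms, at 401.1 against 166.1 CPM. The log2 ratio of Plvap was 1.272 in the pooled cells, above its 0.744, 1.077 and 1.225 in those classes. Aqp1, a water channel, and Emcn, endomucin, differed by 0.02 and 0.03. Ly6a and Ly6c1 belong to a family of near-identical neighbours, so how their reads were divided is uncertain. Basement membrane and matrix genes were higher in 8 of 13 members, with a median of 0.48 (0.36 to 0.54, percentile 99.9) in the pooled cells, above the medians of 0.23, 0.39 and 0.21 in those 3 classes. The type IV collagen chains Col4a1 and Col4a2 were 1.74-fold and 2.18-fold higher, at 870.6 against 500.7 CPM and 446.5 against 204.9 CPM. Sparc, a collagen-binding matricellular protein, stood at 2319 against 1322 CPM, and Fbln2, the elastic fibre protein fibulin-2, at 43.7 against 4.33 CPM (log2 3.33, above its 2.34, 2.72 and 0.48 in the pericentral, intermediate and periportal classes). Lama4, a laminin chain, Timp3, an inhibitor of matrix proteases, and Bgn, biglycan, were lower, at -0.57, -0.55 and -0.52. Vwf and Fbln2 were also naming markers of the large-vessel class. At the lower clustering resolution the matrix median was 0.30.

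AP-1, KLF and immediate-early genes were lower by more than any other list, in 15 of 16 members, with a median of -2.23 (-2.28 to -2.18, percentile 0). Fos and Fosb, subunits of the AP-1 transcription factor, stood at 220.2 against 2215 CPM and 95.2 against 1158 CPM, which is 10.1-fold and 12.2-fold lower. Egr1, an early growth response factor, was 9.21-fold lower, and Zfp36, an mRNA-destabilising protein, 6.28-fold lower. Klf2, a flow-responsive factor of endothelium, stood at 1387 against 2080 CPM, and Nr4a1 was the member that was higher, at 28.1 against 22.4 CPM. This difference rested on part of the control cells. The 1894 control LSEC-like cells of first-step cluster 1 held Fos at 2806 CPM, while the 1031 of first-step cluster 3 held it at 272.9 CPM, close to the cirrhosis level. The transcript Gm42418 stood at 4122 CPM in those cells of cluster 3, against 1524 CPM in cluster 1 and 1472 CPM in cirrhosis. The cells of cluster 3 thus differed from both in other ways. Against the cells of first-step cluster 3 alone the list median was -0.042, and at the lower clustering resolution, which kept 22.2% of the control library as LSEC-like, it was -0.063. These genes took part in the clustering of the first step, so the split of the control cells was partly made by them. The list was also lower in classes outside the endothelium, with medians of -1.96 in Kupffer cell-like and -1.44 in T or NK cell-like cells.

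Among the other lists, interferon-stimulated genes were higher in 14 of 15 members, with a median of 0.87 (0.79 to 0.96, percentile 100). Irf7, the master regulator of type I interferon genes, stood at 64.9 against 19.2 CPM, and Ifit3, an antiviral tetratricopeptide protein, at 71.9 against 23.0 CPM. Genes of the MHC class I pathway were lower in 8 of 8 members, with a median of -0.58. The classical class I genes H2-K1 and H2-D1 stood at 919.3 against 1995 CPM and 1138 against 1976 CPM, and these near-identical genes can share reads. Only 2 members of the MHC class II list were measured, with a median of 0.45 (0.35 to 0.55). Cd74, the invariant chain, stood at 51.5 against 37.1 CPM, H2-Aa at 23.8 against 17.6 CPM and H2-Ab1, below the list's minimum of 20 CPM on average, at 22.5 against 17.1 CPM. T or NK cell-like barcodes held Cd74 at 536.5 against 173 CPM, a higher level in cells of another type. Whether free RNA brought the values of LSEC-like cells was not tested. The list median was 0.15 under the stricter cell filter, 0.22 with doublets kept, 0.25 without a cell filter, 0.24 with mixed clusters added and 0.27 with zones weighted equally. Coagulation genes had a median of 0.92, led by Entpd1, an ectonucleotidase that removes ATP, at 57.5 against 5.89 CPM, with Vwf also higher and F8, coagulation factor VIII, lower at 549 against 895.2 CPM. That median held for the pooled cells only, and those of the pericentral, intermediate and periportal classes were 0.16, 0.0042 and 0.28 over 6, 4 and 5 measured members. Glycolytic genes were higher in 8 of 9 members with a median of 0.42, including Gapdh at 558.8 against 317.2 CPM and Eno1 at 110.8 against 69.3 CPM. Ribosomal protein genes were higher in 70 of 76 members with a median of 0.50, including Rpl15 and Rpl10a at 0.89 and 0.82, although their processed copies make single members uncertain.

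Secreted and signalling genes went in both directions. Angiocrine factors had a median of -0.56 with 6 of 9 members lower, among them Bmp2, a regulator of iron balance, at 1305 against 2301 CPM. Cxcl12, a leukocyte-attracting chemokine, was below the list's minimum on average and so outside that median, at 5.98 against 20.8 CPM. Wnt9b, a ligand of the central vein endothelium, was 4.29-fold higher at 114.5 against 26.7 CPM in the pooled cells (log2 2.10), above its log2 ratios of 1.20, 0.82 and -0.15 in the pericentral, intermediate and periportal classes. Hgf, hepatocyte growth factor, stood at 192 against 76.7 CPM. Genes of the VEGF and angiopoietin list had a median of -0.30, with Angpt2, an antagonist of Tie2, at 11.6 against 29.1 CPM and Esm1, a marker of tip cells, at 93.8 against 30.7 CPM. The log2 ratio of Esm1 was 1.61 in the pooled cells, above its 0.52, 1.34 and 1.51 in those classes. TGF-beta and BMP genes had a median of -0.29, with Ltbp4, a TGF-beta binding protein and naming marker of the periportal class, at 146.5 against 378.9 CPM and Id1, a BMP target, at 366.7 against 188.5 CPM. Chemokines and cytokines had a median of -0.38, and against the control cells of first-step cluster 3 alone that median was 0.52. Ackr3, a scavenging receptor for Cxcl12, stood at 74.8 against 17.6 CPM (log2 2.09, above its 1.46, 1.69 and 2.08 in those classes). Heat shock genes had a median of -0.42, with Dnajb1 at 35.2 against 61.6 CPM and Hspa8 at 732.6 against 1073 CPM, and against first-step cluster 3 alone Dnajb1 differed by 0.079.

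The remaining lists had medians between -0.16 and 0.19, and those of lysosomal, vasoactive, lipid, Notch and mesenchymal genes changed sign under some alternatives. Lysosomal proteins had a median of -0.16, although Cd63, a tetraspanin of late endosomes, was higher at 208.4 against 40.3 CPM. Ctsh, cathepsin H, was below that list's minimum on average and outside its median, at 27.6 against 9.24 CPM. The log2 ratio of Ctsh was 1.58, above its 0.84, 0.865 and 1.28 in the pericentral, intermediate and periportal classes. Vasoactive regulators had a median of 0.05 in the pooled cells and of -0.029, -0.0016 and -0.022 in the pericentral, intermediate and periportal classes. Ramp3, an adrenomedullin co-receptor of that list, stood at 33.0 against 12.4 CPM (log2 1.41, above its 0.88, 0.58 and 0.58 in those classes). Adhesion molecules had a median of 0.13, with Selp, P-selectin, at 45.2 against 12.6 CPM (log2 1.85, and 0.20, 3.43 and 3.05 in the pericentral, intermediate and periportal classes) and Icam1, a ligand of leukocyte integrins, at 49.2 against 117.5 CPM. Lipid-handling genes had a median of 0.19, with Fabp4, a fatty acid binding protein and naming marker of the pericentral class, at 1697 against 904.3 CPM. Antioxidant genes had a median of 0.10, with Hmox1, haem oxygenase, at 64.6 against 34.3 CPM and Gpx1, glutathione peroxidase, at 263.2 against 166.9 CPM. Cell cycle genes had 2 measured members and a median of 0.18, with Stmn1, a microtubule regulator, at 54.6 against 22.4 CPM and Pcna, the replication clamp, at 34.7 against 66.2 CPM. Notch genes had a median of -0.02, with the ligand Dll4, a naming marker of the periportal class, at 82.1 against 151.1 CPM and the ligand Dll1 at 36.8 against 22.6 CPM. Mesenchymal transition genes had a median of -0.03 over 4 members. Among them was the intermediate filament gene Vim, a naming marker of the large-vessel class, at 690.9 against 278.1 CPM. Snai1, a transcription factor of that list, was below its minimum on average, at 11.4 against 25.9 CPM. Mitochondrially encoded genes had a median of 0.07, with mt-Atp8 and mt-Nd6 at -0.70 and -0.62.

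**Figure D2:**
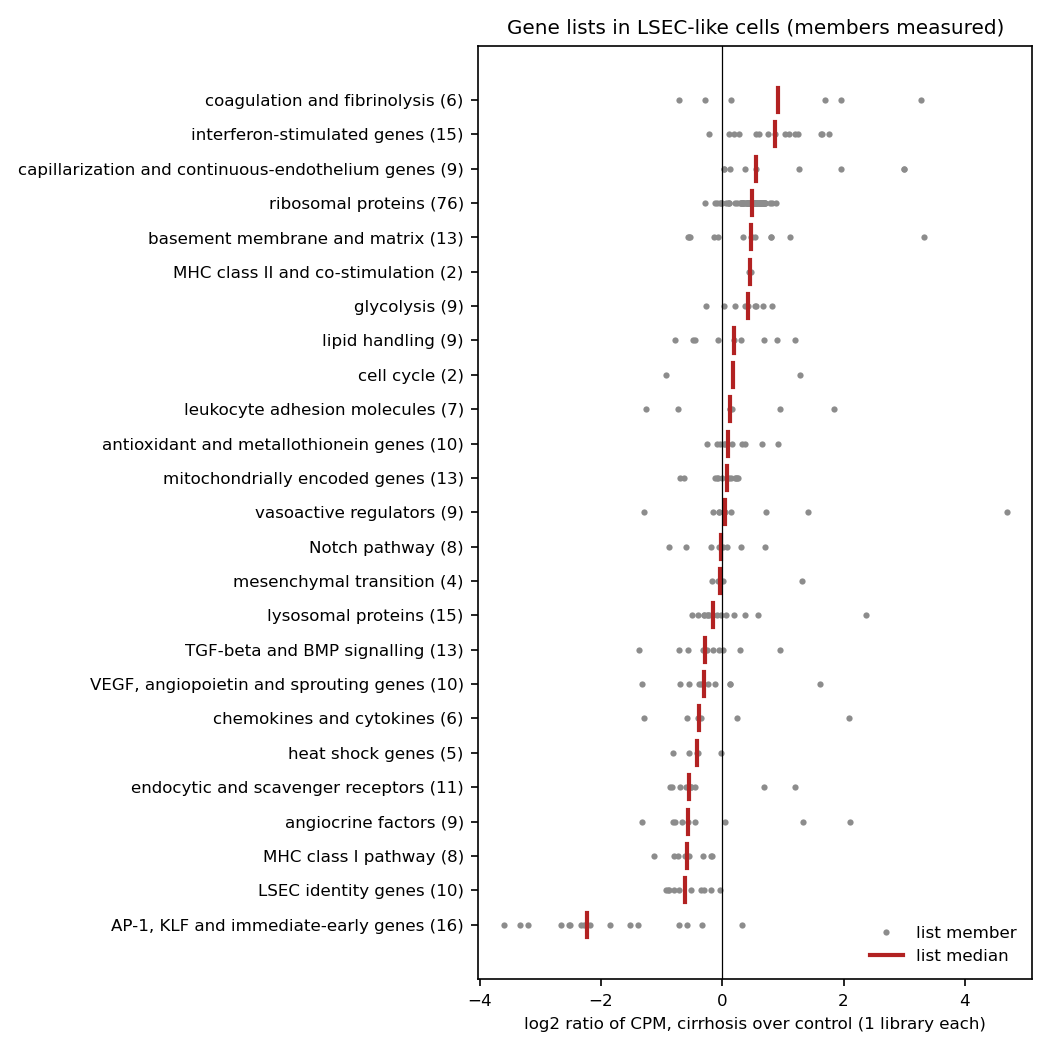
log2 ratio of CPM, cirrhosis over control (x axis), for the members (grey points) and the median (red bar) of each fixed gene list (y axis, number of members measured in brackets) in LSEC-like cells, 1 library per group. The AP-1, KLF and immediate-early list lies lowest at -2.23, and the lists of coagulation and of interferon-stimulated genes lie highest at 0.92 and 0.87 in these pooled cells. The coagulation list had lower medians of 0.16, 0.0042 and 0.28 in the pericentral, intermediate and periportal classes.

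Over all genes at a mean of 50 CPM or more with the same direction in each zone class, the highest ratio was that of Pi16, a peptidase inhibitor on chromosome 17 (29317680 to 29330593, GRCm38), at 233.8 against 2.5 CPM (log2 6.55, 6.17 to 6.95). In the pericentral, intermediate and periportal classes the log2 ratios of Pi16 were lower, at 6.055, 6.017 and 4.501. Ly6c1 (chromosome 15, 75044018 to 75048830) stood at 220.0 against 2.81 CPM and Ednrb (chromosome 14, 103814625 to 103844402) at 1912 against 73.9 CPM. Igfbp5, an insulin-like growth factor binding protein, stood at 213.2 against 10.5 CPM, Plac8 at 93.1 against 7.06 CPM, Flrt2, an adhesion and guidance protein, at 233.2 against 29.3 CPM and C1qtnf6 at 98.9 against 17.9 CPM. Ly6a, Cd34 and Cd63 completed the 10 highest. Ly6c1 and Plac8 were also naming markers of the large-vessel class. The lowest ratio was that of Gm26802 (chromosome 7, 19298260 to 19300770), 19.6-fold lower at 8.25 against 161.5 CPM, which lies beside Fosb (chromosome 7, 19302696 to 19310051). Fosb, Fos (chromosome 12, 85473890 to 85477273), Egr1, Zfp36 and Junb, with Nfkbiz, an inducible regulator of NF-kappaB, made up most of the other lowest genes. Outside the immediate-early group, Cntfr, the receptor of ciliary neurotrophic factor, stood at 16.4 against 103.0 CPM, Rnase4, a secreted ribonuclease, at 28.1 against 147.9 CPM and Prelp, a matrix proteoglycan, at 19.4 against 99.8 CPM. Against the control cells of first-step cluster 3 alone, Junb and Nfkbiz were higher in cirrhosis, by 0.56 and 0.56.

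The second comparison asked whether the differences between cirrhosis and control were alike in the zones of the lobule. LSEC-like cells fell into a pericentral class (371 control and 802 cirrhosis cells), an intermediate class (1634 and 1072) and a periportal class (953 and 1236), named by fixed markers. Scavenger receptors and LSEC identity genes were lower by more in the pericentral class than in the periportal class, and the capillarization list was higher by more. Genes of these lists were not kept out of the second clustering, so they could help to draw the classes compared. Stab1 stood at 596.6 against 1868 CPM in the pericentral class (log2 -1.65, -1.70 to -1.59) and at 1303 against 1613 CPM in the periportal class (-0.31, -0.34 to -0.27). Dnase1l3 stood at 1048 against 3431 CPM (-1.71) in the pericentral and 2335 against 3483 CPM (-0.58) in the periportal class.

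The endocytic list had a median of -0.97 in the pericentral and -0.31 in the periportal class, a difference of -0.66 (interval -0.72 to -0.61), with 10 of 11 members on that side. The exception was Cd36, at 684.2 against 159 CPM in the pericentral and 1689 against 839.1 CPM in the periportal class. LSEC identity genes had medians of -1.20 and -0.36, a difference of -0.84 (-0.89 to -0.79), and 9 of 10 members were on that side. Without the cells of first-step cluster 5, which held 55.7% of the cirrhosis but 2.16% of the control part of the pericentral class, that difference was -0.39. Flt4, the receptor of VEGF-C, stood at 313.5 against 696.2 CPM in the pericentral class and 953 against 866.8 CPM in the periportal class. Capillarization genes had medians of 0.63 and 0.17, a difference of 0.46 (0.26 to 0.59), with 5 of 9 members higher by more in the pericentral class, among them Ly6a, and 4 by more in the periportal class. Vwf was one of the latter, at 194.1 against 142.6 CPM in the pericentral and 52.2 against 4.48 CPM in the periportal class. Basement membrane genes had medians of 0.39 and 0.21 over the 12 members measured in both classes, a difference of 0.18 (0.03 to 0.29), but the pericentral median over all 15 members measured there was 0.23. They had Col4a1 at 1127 against 503 CPM in the pericentral and 718.7 against 481.4 CPM in the periportal class. Immediate-early genes had medians of -2.10 and -2.32, a difference of 0.22 (0.05 to 0.38). Interferon-stimulated genes had medians of 0.44 and 0.87, with Ifit2, an antiviral protein, at 35.9 against 32.1 CPM in the pericentral and 117.4 against 43.4 CPM in the periportal class.

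Among single genes at a mean of 50 CPM or more in both classes, the largest differences in favour of the pericentral class included those of Ly6a, Efnb1, Ednrb and Klf4. Ly6a stood at 2825 against 155.1 CPM in the pericentral and 1297 against 406.1 CPM in the periportal class, and Ednrb at 3443 against 107.9 CPM and 1218 against 123.3 CPM. Efnb1, a ligand of Eph receptors, stood at 539.9 against 192.8 CPM in the pericentral and 345.8 against 403.3 CPM in the periportal class. Klf4, a flow-responsive factor, was 1.21-fold lower in the pericentral class, at 806.8 against 973.3 CPM, and 3.24-fold lower in the periportal class. On the opposite side and at the same minimum, Cyp4b1, a cytochrome P450 enzyme, stood at 66.4 against 825.0 CPM in the pericentral and 556.0 against 1079 CPM in the periportal class. The sulfotransferase gene Sult1a1 was 7.02-fold and 1.67-fold lower, and Olfm1 was 7.19-fold and 1.95-fold lower. Ccnd1, cyclin D1, stood at 89.4 against 181.7 CPM in the pericentral and 406.8 against 268.2 CPM in the periportal class. Clec1b stood at 109.4 against 456.8 CPM and 307.1 against 421.1 CPM.

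Naming markers of the pericentral class went in both directions in its cells. Kit stood at 406.1 against 819.1 CPM and Rspo3 at 190 against 589.3 CPM. Wnt2, Cdh13, Ptgs1 and Fabp4 were lower at -0.72, -1.08, -0.22 and -0.047, and Thbd, Rab3b and Lhx6 higher at 1.52, 1.20 and 0.80. Whether the pericentral or the periportal class held matched cells in both libraries was not tested and cannot be assumed for either. The pericentral class came from first-step cluster 1 for 77.6% of the control part. Its cirrhosis part came from first-step clusters 5 and 0 for 55.7% and 43.1%. The periportal class came from cluster 1 for 75.7% of the control part and from cluster 0 for 97.7% of the cirrhosis part. The genes Dusp5 and Nfkbiz, which respond to stress, led 1 of the 2 clusters joined as the intermediate class. The zone differences were not tested, and the 2 classes could be formed again under 1 of the 7 other cell filters and clusterings tried. Without centring each library, the pericentral class held 10 control and 1181 cirrhosis cells and the periportal class 1111 and 30. Those classes thus largely followed the libraries. At the lower resolution the pericentral class held 21 control and 623 cirrhosis cells, and no periportal class was formed.

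**Figure D3:**
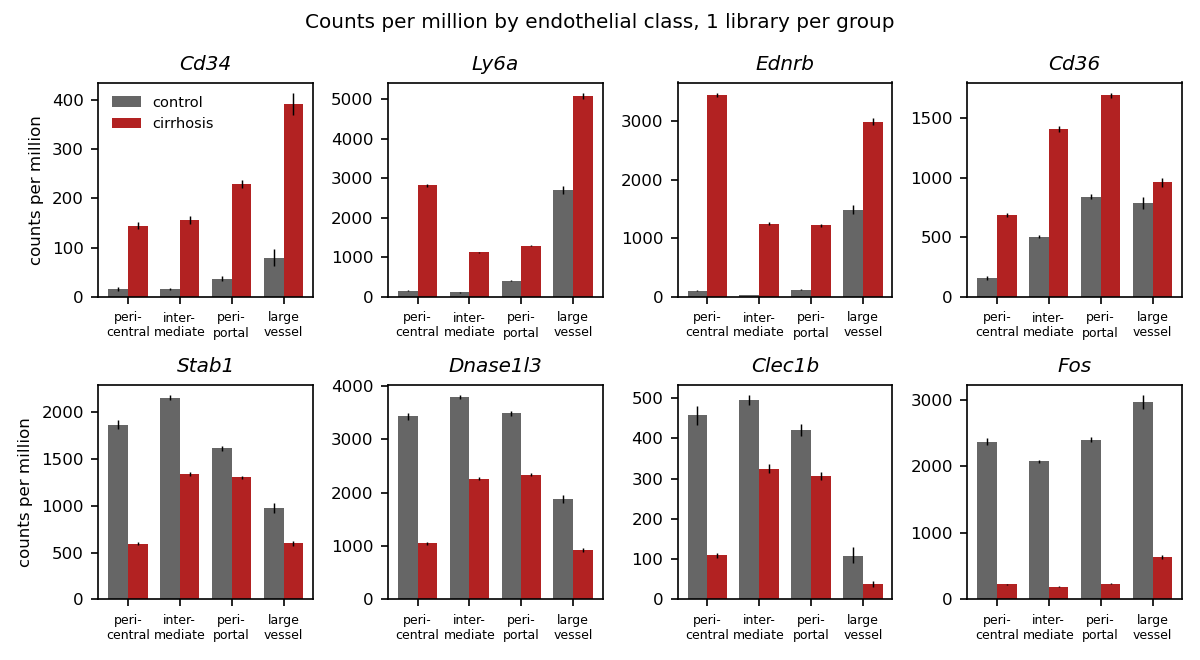
CPM (y axis, starting at 0) of 8 genes in 4 endothelial classes (x axis) of the control (grey) and cirrhosis (red) libraries, 1 library per group, with exact 95% Poisson intervals as lines. Stab1, Dnase1l3 and Clec1b were lower by more in the pericentral class (Clec1b 109.4 against 456.8 CPM) than in the periportal class (307.1 against 421.1 CPM), and Fos was lower in each class.

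The third comparison concerned large-vessel endothelial-like cells, 124 in the control and 295 in the cirrhosis library. Basement membrane and matrix genes were higher in 12 of 17 members, with a median of 0.35 (0.17 to 0.56, percentile 99.8). Col4a2 stood at 426.3 against 187.2 CPM (log2 1.19, 0.98 to 1.40), Sparc at 2317 against 1239 CPM and Fbln2, a naming marker of this class, at 384.3 against 206.4 CPM. Mgp, matrix Gla protein and also a naming marker, was lower at 61.6 against 146.1 CPM. Capillarization genes were higher in 7 of 9 members with a median of 0.52, including Cd34 at 391.1 against 78.7 CPM and Vwf, a naming marker, at 1086 against 426.0 CPM. The genes with the highest ratios were Adamts5, an aggrecan-cleaving protease, at 130.0 against 12.3 CPM (log2 3.41, 2.65 to 4.29), Pi16 at 233.7 against 26.2 CPM, Ly6c1, a naming marker, at 1086 against 142.6 CPM, Rflnb at 251.3 against 36.7 CPM and Cnmd, chondromodulin, at 134.9 against 23.6 CPM. The lowest were the chemokine genes Ccl3 and Ccl4, with 3 and 5 UMIs in the cirrhosis cells against 144 and 151 in the control cells (log2 -7.01, -9.30 to -5.43, and -6.34, -7.98 to -5.09), Gm26802 at 17.6 against 258.0 CPM, Hspa1a, a heat shock gene with a near-identical copy, at 23.1 against 220.4 CPM, and Atf3, a stress-responsive factor, at 21.5 against 188.1 CPM. Interferon-stimulated genes had a median of 0.92 and heat shock genes one of -1.64, with 7 of 7 members lower. First-step cluster 9 held 90.5% of the cirrhosis cells but 39.5% of the control cells, and 46.0% of the control cells came from cluster 1. Summed LSEC markers stood at 7346 against 13530 CPM in this class, and at 16290 against 26480 CPM in LSEC-like cells. A different mix of cells in the 2 libraries was therefore not told from a change in expression. Without centring each library before clustering, the matrix median of this class was -0.00062. The median of LSEC identity genes in this class was then 0.058, outside its interval of -0.66 to -0.48.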

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

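The tests of central-vein cells, of first-step cluster 5 and of both reporter transcripts, the levels that free RNA would bring and the split of the control cells were chosen only after the results were seen. Differences between zones were not tested, since each zone held 1 library per group. Efnb1 and Ccnd1 went in opposite directions in the pericentral and periportal classes, with differences of log2 ratios of 1.71 and -1.62. The same held for the antigen presentation genes Cd74 and H2-Aa with -0.88 and -1.09, and for the median of the MHC class II list over both genes with -0.98. Fabp4, a naming marker of the pericentral class, differed by -1.52, but its ratio of -0.047 in that class turned positive with the shift of 0.11 that scaling by the median of ratios brings. Mitochondrially encoded genes had medians that differed by 0.23, and the periportal one of -0.044 turned positive with the shift of 0.054 under that scaling, so the opposite signs depended on it. The eGFP transcript, outside the main measurement, stood at 512.7 CPM in the 51 neutrophil-like barcodes of the cirrhosis library against 182.3 CPM in the 20 of the control library.

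The lower immediate-early transcripts of the cirrhosis LSEC-like cells could come from how the preparations were handled, from depth or from the disease. Handling would touch other cell types, and the list median lay below -0.5 in 4 of 5 non-endothelial classes. In B cell-like cells it was -0.34, where scaling by the median of ratios moved the median of all genes by -0.74. In Kupffer cell-like cells Fos stood at 2793 CPM in the control library, above the 407.8 CPM that free LSEC RNA would bring. In hepatocyte-like barcodes Fos stood at 204.7 CPM, below the 366.2 CPM from that source. Depth as the whole cause is argued against by a median of -2.45 in cells of 6000 to 12000 UMIs, a window above most control cells of first-step cluster 3. The control library held both states, since its cells of that cluster, at a median of 4800 UMIs, had Fos at 272.9 CPM and those of cluster 1, at 7945 UMIs, had 2806 CPM. Handling and an effect of cirrhosis on all cell types stay open, because each group was 1 preparation.

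The larger deficit of LSEC identity genes in the pericentral class might reflect more central-vein cells in its cirrhosis part, a difference in depth, or a response of that zone. Central-vein cells as the whole cause would bring higher venous markers, but 4 of 7 were lower, namely Rspo3, Bgn, Vcam1 and Cdh13, of which Rspo3 and Cdh13 also name the class, and Wnt9b alone was higher at 352.6 against 153.1 CPM. Cells of first-step cluster 5 fit as a source of much of the difference, which was -0.39 without them; the cluster, with pericentral LSEC markers at a mean log2 fold of 2.66, venous markers at 1.5 and general LSEC markers at -0.48, gave 447 of 802 cirrhosis but 8 of 371 control cells of the class, but the first step did not leave identity genes out. Depth is argued against by a difference of -0.73 in cells of 6000 to 12000 UMIs, against -0.84 in all cells. Whether that cluster held vein-lining cells of changed profile or LSECs changed by injury stays open, and so does a class that collects different cells in each library, since most reclusterings did not return both zones.

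The reporter transcripts tdTomato and eGFP were both found in non-endothelial classes, which could reflect free RNA or sorted cells that carried tdTomato. Free RNA is argued against for tdTomato, because its level in LSEC-like cells was at most 0.0168 of the lowest level in T or NK, Kupffer and cholangiocyte-like cells. T or NK cell-like cells held 91.2 and 88.8 CPM of tdTomato, against 0.536 and 0.661 CPM in LSEC-like cells of the control and cirrhosis library. Among those 3 classes the ratio of eGFP to LSEC marker counts reached 2.23 times that of LSEC-like cells, in T or NK cell-like cells of the cirrhosis library. In Kupffer cell-like cells it lay at 0.882 and 0.801 times that of LSEC-like cells. Outside the test, the ratio itself was 0.39 in neutrophil-like, 0.085 in B cell-like and 0.094 in LSEC-like cells of the cirrhosis library. In the control library these were 0.061, 0.094 and 0.066. Whether free endothelial RNA was the only source of eGFP cannot be told apart from its own transcription, since the classes disagreed, and no biological explanation was tested.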

How the results depend on the processing

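The alternatives that kept cells with other types' transcripts, added mixed clusters, weighted zones equally, took cells of 6000 to 12000 UMIs or took one part of the control cells were chosen after the data had been seen. No paired analysis was possible because each group had 1 library and no test was made. Over 15 alternatives the LSEC-like medians ranged from -0.64 to -0.45 for endocytic, 0.49 to 0.63 for capillarization, -0.79 to -0.43 for identity, 0.30 to 0.56 for matrix, 0.15 to 0.54 for MHC class II and -2.53 to -0.042 for immediate-early genes, without a change of sign. Zone differences had 5 alternatives, because the other cell filters and clusterings returned no pericentral and periportal class of 50 cells per library that passed the marker check. They ranged from -0.63 to -0.48 for endocytic, 0.41 to 0.53 for capillarization, 0.12 to 0.24 for matrix and 0.20 to 0.27 for immediate-early genes. The large-vessel class had 8 alternatives. Under the stricter filter, no filter, doublets kept, the lower and the higher resolution and no centring at least 1 zone class was not formed or failed the marker check, and LSEC-like cells were still summed. Of 70 genes named in LSEC-like cells, 67 had the same sign at the lower resolution and against first-step cluster 3 alone, and 70 under each other alternative. The fold moved by more than 1.5 times for 22 genes against first-step cluster 3 alone, 16 at the lower resolution, 5 in cells of 6000 to 12000 UMIs and 4 with zones weighted equally, where 14, 19, 19 and 25 of the 70 genes stayed within their intervals. It did so for 2 genes each without centring and against cluster 1 alone, and for 1 under the stricter filter. The 10 zone genes kept their sign in 80 of 80 pericentral and 50 of 50 periportal values, and the 10 large-vessel genes in 78 of 78. Depth limits genes of few counts, such as Ccl3 in large-vessel cells, with 3 UMIs in cirrhosis and an interval of -9.30 to -5.43.

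Scaling by the median of ratios gave LSEC-like medians of -0.47 for endocytic, 0.63 for capillarization, -0.53 for identity, 0.56 for matrix and -2.15 for immediate-early genes, and a zone difference of -0.61 for endocytic genes. It turned the medians of the Notch pathway (0.055) and mesenchymal transition (0.048), as did the total without mitochondrial and ribosomal genes (0.039 and 0.032) and cells of 6000 to 12000 UMIs (0.044 and 0.027). The Notch pathway also turned at the lower resolution (0.016), without centring (0.0034) and, to just above 0, against first-step cluster 3 alone, and mesenchymal transition with zones weighted equally (0.030) and against first-step cluster 1 alone (0.0096). Without mitochondrial and ribosomal genes in the total these were -0.49, 0.61, -0.55, 0.54 and -2.17 for the LSEC-like medians. Equal weight per cell gave -0.51 for endocytic, -0.56 for identity and -2.11 for immediate-early genes, and -0.58 for the zone difference of endocytic genes. The stricter filter gave -0.58 for endocytic, -0.65 for identity and 0.15 for MHC class II genes. No filter gave -0.58 for identity and 0.25 for MHC class II genes and an LSEC-like share of 46.1% of the cirrhosis library. Doublets kept gave 0.22 for MHC class II genes and a share of 61.1% of the control library. The higher resolution gave a share of 45.0% of the cirrhosis library.

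The lower resolution gave -0.63 for endocytic, -0.75 for identity, 0.30 for matrix and -0.063 for immediate-early genes and shares of 22.2% and 47.3%, with 2295 control cells, of a cluster with Fos at 1785 CPM, left out as a mixture. It turned vasoactive (-0.0080), chemokine (0.47) and lipid genes (-0.058), and Nfkbiz (0.54), Junb (0.43) and Dnajb1 (0.062). Against control cells of first-step cluster 3 alone the medians were -0.64 for endocytic, 0.60 for capillarization, -0.79 for identity and -0.042 for immediate-early genes. Chemokine (0.52) and lipid genes (-0.053), Nfkbiz (0.56), Junb (0.56) and Dnajb1 (0.079) turned there too. Against cluster 1 alone they were -0.52 for identity and -2.53 for immediate-early genes. Without centring, the large-vessel medians turned for matrix (-0.00062), lysosomal (0.016) and identity genes (0.058). For these and the following values the cause was not tested.

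Cells with other types' transcripts kept gave a zone difference of -0.61 for endocytic genes. Mixed and unnamed clusters added gave -2.10 for immediate-early and 0.24 for MHC class II genes and turned lysosomal genes (0.034). Zones weighted equally gave 0.49 for capillarization, -0.63 for identity, -2.35 for immediate-early and 0.27 for MHC class II genes and turned vasoactive genes (-0.012). Cells of 6000 to 12000 UMIs gave -0.45 for endocytic, 0.50 for capillarization, -0.43 for identity, -2.45 for immediate-early and 0.32 for MHC class II genes, and -0.48 for the zone difference of endocytic genes.

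Of the other 19 lists in LSEC-like cells, 267 of 285 values had the sign reported and 7 turned where the interval had excluded 0. Of 24 other lists in large-vessel cells these numbers were 175 of 192 and 2, and of 21 other zone differences 98 of 105 and 0.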

Other observations

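The genes named here for Kupffer cell-like cells, and the comparison of list medians across other classes, were chosen after the data had been seen, and no difference was tested. Kupffer cell-like cells numbered 121 in the control and 297 in the cirrhosis library. The lipid-handling list had a median of 0.12 there, with 7 members higher and 6 lower, and the genes below are single examples. Gpnmb, a macrophage glycoprotein, stood at 407.7 against 3.45 CPM (log2 6.88, interval 5.76 to 8.33). Trem2, a lipid-sensing receptor, stood at 646.0 against 59.2 CPM, Mmp12, macrophage elastase, at 428.0 against 51.8 CPM and Fabp5, a fatty acid binding protein, at 558.0 against 84.0 CPM. Spp1, osteopontin and also a naming marker of cholangiocytes, stood at 268.2 against 20.7 CPM. Cd163, a haemoglobin scavenger receptor, stood at 10.4 against 464.1 CPM (log2 -5.49, -5.88 to -5.11), Cxcl13, a B cell chemokine, at 7.52 against 258.8 CPM, and Timd4, a phosphatidylserine receptor and naming marker of this class, at 8.18 against 306.0 CPM. Ms4a7, a naming marker of monocytes or macrophages, stood at 532.6 against 68.4 CPM. Whether the class held the same type of macrophage in both libraries was not tested. The immunoglobulin genes Ighg2c and Igha stood at 1.0 against 2173 CPM and 971.0 against 33.4 CPM. Igha was also a leading gene of the B cell-like cluster, and whether these transcripts arose in the Kupffer cell-like cells was not tested. Endothelial Stab2 was present in the class at 374.4 CPM in the control and 251.3 CPM in the cirrhosis library. A mixed cluster of endothelial and Kupffer transcripts, with 240 control and 537 cirrhosis barcodes, stayed outside the class.

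Interferon-stimulated genes had medians of 0.81 in cholangiocyte-like, 0.44 in Kupffer cell-like and 1.16 in hepatocyte-like barcodes, the last over 6 measured members, and of -0.02 in T or NK cell-like cells. In B cell-like cells the median of 0.48 over 4 members lay below the 0.79 of all genes at a mean of 20 CPM or more. In hepatocyte-like barcodes the median of all genes at that minimum was -0.28.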
